A study of Mus musculus with 24 samples.

How the data were processed

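RNA was measured by poly(A)-selected, stranded RNA sequencing of whole spinal cord from 24 mice. The animals carried either 2 wild-type copies of Gars or 1 mutant copy, and 2, 1 or 0 intact copies of Gcn2 (gene symbol Eif2ak4). Genotype and sex were read from the sample labels. Each library was taken as a separate animal, since the labels give each its own number and sex, although they do not say so in words. Their titles begin with a number that 1 to 6 libraries share, whose meaning is not stated. The labels name more than 1 library kit and reagent version without saying which library had which.

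The deposited values are expected counts per gene, made with RSEM 1.2.12 and Bowtie2 2.2.0, per the submitters' processing notes. An expected count shares out a read that matches several genes or transcripts, so it need not be whole. In these files 72.0% of the non-zero values lay within 0.005 of a whole number. Near-identical genes, such as a gene and its processed pseudogene, share reads in such counts, and their separate values are uncertain. The genome build and gene annotation behind the files are not given in the sources used here. The files list 38924 Ensembl genes each, of which 37607 have the same identifier in GENCODE release M21 of the mouse build GRCm38. Symbols and positions below come from that release. Genes without a match held 0.26% of all counts. Of the 24052 genes with 1 transcript that could be matched, 75.9% had the same length in both.

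The deposited expected counts were rounded to whole numbers before testing. Library totals ran from 19.7 to 32.4 M (M, mega). Genes too low for a test were removed with edgeR's filterByExpr by genotype group, which left 17409 genes. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates. A single fit held all 24 libraries, 6 genotype groups and sex, because sex was unevenly spread over the groups. Every adjusted p given for a gene is from that test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p below 0.05. Values after ± on a log2 fold change are standard errors, and those on CPM (counts relative to the library total, scaled by TMM) are SDs over the libraries of a group. The common biological coefficient of variation was 0.225.

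The comparisons, the covariates, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes are named by that rule. Eif2ak4 and Gars are named in every comparison. Of the called genes outside the windows described below, with a mean CPM of at least 1 and a symbol that is not provisional, up to 10 that rose and up to 10 that fell with the largest fold changes are open to naming, and inside the chromosomal window of a tested allele up to 4 with the smallest p. In the difference between Gcn2+/- and Gcn2+/+ mice and in the effects of 1 lost Gcn2 copy, the up to 5 called genes with the smallest p are named instead, of any symbol. The windows reach 20 Mb to each side of Gars and of Eif2ak4, since sequence from the donor strain can stay linked to an allele through crosses. Of each gene list described, up to 4 members with the smallest p are named. A gene named outside this rule is said to be chosen after its values were seen.

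Gene lists were written from general knowledge of cell types and pathways. One of them, of stress genes known from neuropathy motor neurons, comes partly from work of the same laboratory and is not independent evidence of its direction. All its genes except B4galnt2 are also on the list of ATF4 and integrated stress response targets, so these lists are not separate evidence. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Adjusted p values of lists were adjusted over the lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone.

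The fits were tested on simulated counts drawn from the means and totals of these libraries. Changed genes were picked from those with a mean CPM of at least 1, so the recovered shares hold for such genes only. The simulated libraries held no differences by title number or tissue content, which the real ones have. The recovered shares and false calls below therefore leave such differences out of account. For the Gars effect with Gcn2 intact, 61.2% of genes changed 1.5-fold, 80.6% changed 2-fold and 97% changed 4-fold were recovered among 17255 simulated genes, with 2.45% false calls. For the difference of that effect between Gcn2 genotypes, 26.9%, 65.7% and 93.9% were recovered among 17250 genes, with 6.06% false calls. The Gars effect in Gcn2-/- mice had 6.1% false calls, also above the 5% of the threshold. The list test gave an adjusted p of 4.81e-17 for a list lowered 1.25-fold and called 0 of 100 random lists. Genes were drawn independently in that simulation, so it does not test false calls of lists whose members vary together.

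Libraries of the same group were compared for duplicates, and the smallest chi-square per degree of freedom between any pair was 12.3, far above counting noise. Xist and 4 Y-linked genes were checked against the sex in the labels, and 0 libraries mismatched. Genes at 0 to 3 counts in a group are given as ratios of summed counts with 95% intervals, or as bounds against 3 counts over the group, and these cover counting error only. Alternatives comprised DESeq2 1.42.0 in place of edgeR, its size factors, voom in limma, other filters, no sex term, fewer groups in the fit, the number in the library titles as a block, a surrogate variable from sva 3.50.0, and leaving out each library. Title numbers 25004, 25005 and 25006 belong to 1 library each, so the block fits those libraries exactly and leaves them no part in a comparison. They are Gcn2+/-, wild-type Gars replicate 3, Gcn2+/- Gars mutant replicate 4 and Gcn2-/-, wild-type Gars replicate 3. Transcripts were compared for paralogs with BLAST+ 2.17.0.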

Results

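Whole spinal cord was profiled in 24 mice aged 8 weeks, 13 male and 11 female. Gars encodes glycyl-tRNA synthetase, which charges tRNA with glycine, and dominant Gars mutations cause Charcot-Marie-Tooth disease type 2D, a neuropathy of motor and sensory axons. Gcn2 is the kinase that senses uncharged tRNA and stalled ribosomes and phosphorylates eIF2 alpha, which starts the integrated stress response. The design crosses a dominant Gars mutation with loss of Gcn2, and so asks how much of the response to mutant Gars in the spinal cord needs Gcn2. The groups were Gcn2+/+ mice with wild-type Gars (4 animals) or mutant Gars (4), Gcn2-/- mice with wild-type Gars (3) or mutant Gars (5), and Gcn2+/- mice with wild-type Gars (4) or mutant Gars (4). Total counts averaged 28.1, 27.9, 26.3, 28.2, 21.4 and 24.5 M (M, mega) in these groups, in that order, with single libraries between 19.7 and 32.4 M. The precision of each value below is that of 3 to 5 animals per group.

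The targeted gene was checked first. Eif2ak4 (ENSMUSG00000005102, chromosome 2, 118388618 to 118475234 on GRCm38) had 31.2 ± 2.39 CPM (SD, n = 4) in wild-type mice and 32 ± 1.01 (n = 4) in Gars mutants with intact Gcn2. In Gcn2-/- mice it had 13.6 ± 1.91 CPM (n = 3) with wild-type Gars and 13 ± 1.28 (n = 5) with mutant Gars. Gcn2+/- mice lay between, at 22.7 ± 0.895 (n = 4) and 22.4 ± 1.41 CPM (n = 4). Single libraries ran from 28.9 to 34.4 CPM in Gcn2+/+, wild-type Gars mice and from 11.4 to 15 CPM in Gcn2-/-, wild-type Gars mice, so the Gcn2 genotypes were separate in the data as in the labels. Gars (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500) had group means between 135 and 148 CPM. Its allele changes the protein, so this level does not check the Gars labels.

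In mice with intact Gcn2, mutant Gars raised genes of the integrated stress response and lowered genes of motor neurons. Fgf21, a hormone that cells secrete under metabolic and mitochondrial stress, had 3.93 ± 1.15 CPM in the 4 mutants and a single count over the 4 wild-type libraries. The ratio of summed counts was 437 with a 95% interval of 78 to 17292. Adm2, an adrenomedullin-like peptide, had 112 counts against 1, a ratio of 108 (19 to 4313). Cdsn, the gene of corneodesmosin, rose by 3.59 ± 0.38 on the log2 scale, and the stress-induced chromatin protein gene Nupr1 by 2.53 ± 0.51. Nupr1 lost its call in 6 of 21 alternatives, and its log2 change with mutant Gars was 0.12 in Gcn2+/- mice. Calca, which encodes the peptide CGRP, fell from 23.2 ± 1.72 to 5.14 ± 1.39 CPM, a log2 change of -2.25 ± 0.19 (adjusted p = 1.61e-06).

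Of the 51 tested ATF4 and integrated stress response targets, 8 rose and 0 fell, and 18 rose when adjusted over the list alone. The list's median log2 change was 0.22, its camera adjusted p was 2.12e-11, and its adjusted p was 0.0226 with an estimated correlation. Atf4 itself, the transcription factor of this response, rose by 0.44 ± 0.07, and Sesn2, a leucine sensor that restrains mTORC1, rose by 0.63 ± 0.09. Of 9 stress genes known from neuropathy motor neurons, a list that is not independent evidence of its direction, 4 rose, and 7 rose when adjusted over the list alone (median 0.63, adjusted p = 0.00154 with an estimated correlation). Among them B4galnt2, a glycosyltransferase gene, rose by 4.12 ± 0.65, and only it is not also on the list of stress response targets. Of 23 cytosolic tRNA synthetase and tRNA export genes, 2 rose, namely Wars (0.24 ± 0.05) and Cars (0.32 ± 0.07), and 5 rose when adjusted over the list alone. Their camera adjusted p was 0.00503, but the adjusted p was 0.626 with an estimated correlation. Of 21 genes of the unfolded protein response of the endoplasmic reticulum, 0 passed the edgeR test, none when adjusted over the list alone, and 18 lay below 0 (median -0.15; p = 0.387 unadjusted and adjusted p = 0.794, both with an estimated correlation). Dnajc3, an inhibitor of eIF2 kinases, was at -0.28 ± 0.11.

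Of 31 tested motor neuron genes, 11 fell and 0 rose, while 15 fell and 2 rose when adjusted over the list alone. The median was -0.31, and the adjusted p was 0.00154 with an estimated correlation. Besides Calca, the CGRP gene Calcb fell by 1.67 on the log2 scale (SE 0.16), and Chodl, a marker of fast motor neurons, went from 28.6 ± 5.87 to 6.45 ± 1.16 CPM. Nefl, the light neurofilament chain, fell by 0.58 (SE 0.07). Other large decreases were those of Uts2b (-1.95 ± 0.29), a urotensin peptide, Slc10a4 (-1.16 ± 0.16), a vesicular transporter of cholinergic and monoaminergic neurons, the potassium channel gene Kcnj14 (adjusted p = 3.78e-05), Amhr2 (-1.13 ± 0.25), which encodes the receptor of anti-Müllerian hormone, Dio2 (-1.05 ± 0.21), which activates thyroid hormone, Ahnak2 (-0.96 ± 0.14) and Rspo2 (-0.94 ± 0.16), a Wnt enhancer.

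Genes known from sensory neurons moved both ways. P2rx3, the ATP receptor of nociceptors, rose by 1.86 ± 0.21 and Avil, an actin regulator of sensory neurons, by 2.43 ± 0.43, while Calca fell. Tlx3, a transcription factor of dorsal horn neurons, rose by 0.81 ± 0.18. Of the 11 tested genes of this list 3 rose and 1 fell, 4 and 1 when adjusted over the list alone, and camera gave an adjusted p of 0.22. Further increases were those of Stbd1 (1.80 ± 0.24), a glycogen-binding protein gene, Scara3 (1.26 ± 0.27), a scavenger receptor gene, Tead3 (0.80 ± 0.16), Skor2 (0.73 ± 0.15), Pdzrn3 (0.73 ± 0.16) and Cyb5r1 (0.63 ± 0.10).

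Markers of other tissues also differed between these libraries, without a called gene. The mean log2 CPM of the Schwann cell and nerve root genes was 4.13 and 4.84 in Gars mutants 2 and 4, against 1.40 and 2.22 in mutants 1 and 3 and 1.07 to 1.38 in the wild-type libraries. These 19 genes had a median of 1.45 (0 called, 9 up when adjusted over the list alone) and the 22 genes of meninges and fibroblasts one of 2.37 (0 called, 14 up), with adjusted p of 0.626 and 0.736 with an estimated correlation. Reactive astrocyte genes (18 tested, 0 called, none over the list alone) had a median of 0.53, activated microglia and complement genes (21, 0 called, 4 up and 1 down) one of 0.48, and pericyte and smooth muscle genes (17, 0 called, 5 up) one of 0.39. Each of these had an adjusted p of 0.626 with an estimated correlation, as had the 13 mitochondrially encoded genes, whose median was -0.28 (0 called, none over the list alone). Single members were Serping1 (2.48 ± 0.78, adjusted p = 0.13), Apoe (0.48 ± 0.11, 0.0502), Egr2 (4.14 ± 1.38, 0.147), Aldh1a2 (3.27 ± 1.01, 0.127), Myh11 (0.83 ± 0.24, 0.108) and mt-Atp8 (-2.13 ± 0.67, 0.131).

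In all, 110 genes were called for the Gars effect with intact Gcn2, 37 up and 73 down, of 17409 tested by edgeR. With these 2 groups alone in the fit 11 were called, 6 up and 5 down, with the 4 listed genotypes 57, without a filter on low genes 72, without the sex term 201 and with DESeq2 663. Leaving out single libraries gave 600 calls without wild-type replicate 1, 52, 47 and 71 without wild-type replicates 2, 3 and 4, and 58 and 48 without Gars mutant replicates 1 and 2. With a Schwann gene score as a covariate, an alternative chosen after seeing the data, 39 genes were called, with 5 of the stress response targets up and 10 motor neuron genes down. In that alternative the stress response list had an adjusted p of 0.0531 and the motor neuron list 0.00302 with an estimated correlation.

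**Figure D1:**
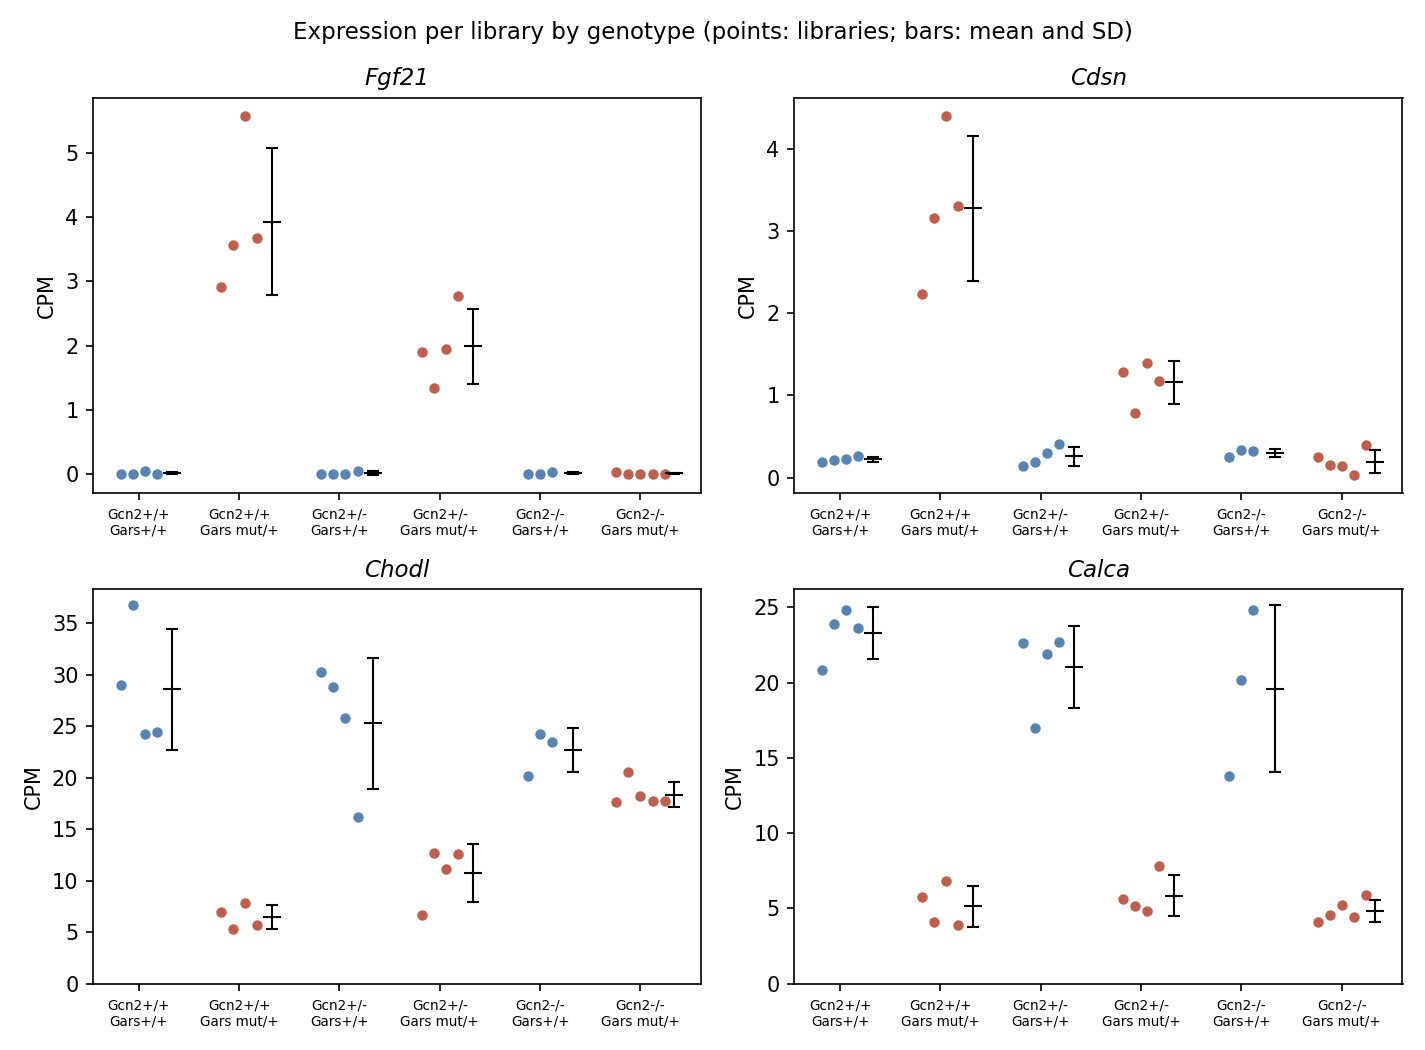
CPM per library of selected genes in the 6 genotype groups, blue for wild-type and red for mutant Gars, with bars for the group mean and SD; axes marked as log are logarithmic. Calca was low in Gars mutants of each Gcn2 genotype, while Fgf21 stayed at 0 to 1 counts per library in Gcn2-/- Gars mutants.

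In mice without Gcn2, mutant Gars lowered Calca, a CGRP gene, in every fit tried and called 1 other gene, its relative Calcb, in the main fit. Calca was at 19.6 ± 5.53 CPM in 3 mice with wild-type Gars and 4.84 ± 0.711 in 5 with mutant Gars, a log2 change of -1.96 ± 0.19 (adjusted p = 1.97e-05), and Calcb fell by 1.00 on the log2 scale (SE 0.16, adjusted p = 0.0248). Fgf21 had 1 count over all libraries in each of these groups, and Adm2 had 0 in both, which allows at most 3 counts over each group. Chodl had 22.6 ± 2.14 CPM with wild-type and 18.3 ± 1.21 with mutant Gars.

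Of the 51 stress response targets 0 were called in either direction, also when adjusted over the list alone, and 39 lay above 0. The median was 0.10, and the adjusted p was 8.66e-04 by camera and 0.536 with an estimated correlation. Atf4 was at 0.23 ± 0.07 (adjusted p = 0.878), Pycr1, an enzyme of proline synthesis, at 0.63 ± 0.24 and Slc3a2, the heavy chain of amino acid transporters, at 0.22 ± 0.09. Of the 9 neuropathy stress genes 0 were called (median 0.18, camera adjusted p = 0.057). Among 31 motor neuron genes 2 fell, Calca and Calcb, while 5 fell and 2 rose when adjusted over the list alone, with a median of -0.07 and an adjusted p of 0.536 with an estimated correlation. Nefl was at -0.26 ± 0.07. Microglia genes (20 tested, 0 called, none over the list alone) had a median of 0.29 and genes of bone marrow and neutrophils (9 tested, 0 called, none over the list alone) one of -1.15, each with an adjusted p of 0.983 with an estimated correlation. Tmem119, a microglial surface gene, was at 0.42 ± 0.23, and the neutrophil granule gene Ngp at -1.87 ± 0.99.

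At an unadjusted p below 0.05, 757 genes passed in this comparison, and DESeq2 called 32. Leaving out single libraries left 1 call without wild-type replicates 1 or 2 and without mutant replicates 1, 2, 3 or 4. Calcb was the gene lost in each of these. Its call also ended with the title number as a block (-0.87, adjusted p = 0.465), with its own 2 groups alone (-0.94, 0.86), with the 4 listed genotypes (-0.98, 0.223), with a surrogate variable (-0.98, 0.0562), with title numbers in 2 sets (-0.95, 0.128) and without wild-type replicate 3 (-0.91, 0.214).

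Genes called with intact Gcn2 were looked up in the other Gcn2 genotypes, which share no libraries with them. Of the 37 that rose, 31 were above 0 in Gcn2-/- mice, as were 61% of the uncalled genes above 0 with intact Gcn2, and their median went from 0.58 to 0.12. Of the 73 that fell, 58 were below 0, as were 60.3% of the uncalled genes below 0 with intact Gcn2, with a median of -0.12 against -0.53. In Gcn2+/- mice 24 of the 37 were above 0 and 49 of the 73 below, against 37.3% and 41.5% of the uncalled genes that lay above and below 0 with intact Gcn2, with medians of 0.12 and -0.07. The medians thus lay nearer to 0 in both genotypes, as the choice of called genes alone would also bring about. The shares of uncalled genes differed between the genotypes, so like medians do not mean that as much of the effect remained. In the same direction, 14 of the 37 and 28 of the 73 had an unadjusted p below 0.05 in Gcn2+/- mice, with 4 and 15 called. In Gcn2-/- mice these were 6 and 18, with 0 and 2 called. Of all 17409 tested genes, 2562 and 757 passed that unadjusted level in Gcn2+/- and Gcn2-/- mice, in either direction.

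The difference between the Gars effects in Gcn2-/- and Gcn2+/+ mice was tested directly. Kcnj14, which encodes an inward rectifier potassium channel, lost its decrease, with 21.3 ± 1.94 CPM in wild-type and 9.98 ± 0.906 in mutant Gars mice with Gcn2, and 18.6 ± 2.76 and 19.9 ± 1.34 CPM without it, a difference of 1.19 ± 0.18 on the log2 scale (adjusted p = 0.00963). Cdsn lost its increase, from 0.225 ± 0.0317 to 3.27 ± 0.885 CPM with Gcn2 and from 0.301 ± 0.0459 to 0.197 ± 0.136 without, a difference of -4.04 ± 0.57 (adjusted p = 0.00963). These 2 were the genes called, of 858 at an unadjusted p below 0.05, and DESeq2 called 35.

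As a group, motor neuron genes were less lowered without Gcn2. None of the 31 passed over all genes and 12 were up when adjusted over the list alone, with a median difference of 0.29 and an adjusted p of 0.00828 with an estimated correlation. Among them were Chodl (1.75 ± 0.30, adjusted p = 0.0535), the neurofilament gene Nefh (0.54 ± 0.10, 0.108), the peripherin gene Prph (0.81 ± 0.16, 0.132) and Chat (0.51 ± 0.11, 0.137), the enzyme of acetylcholine synthesis. The 9 neuropathy stress genes all lay below 0 (0 called, 3 down when adjusted over the list alone, median -0.70, adjusted p = 0.0141 with an estimated correlation), with B4galnt2 at -4.06 ± 1.11 (0.605). Of the 51 stress response targets 1 was down, Cdsn, and 5 down and 1 up when adjusted over the list alone, with an adjusted p of 2.45e-04 by camera and 0.35 with an estimated correlation. Sesn2 was at -0.45 ± 0.13 and Map1lc3b, an autophagy protein gene, at 0.40 ± 0.12. Reactive astrocyte genes (median -0.75, 0 called, none over the list alone) and Schwann cell genes (median -1.42, 0 called, none over the list alone) had adjusted p of 0.475 and 0.601 with an estimated correlation, with Gfap at -0.57 ± 0.27 and Scn7a at -2.10 ± 0.99.

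Calls fell to 0 with the title number as a block and without wild-type replicate 4 or Gcn2-/-, wild-type Gars replicate 2. They fell to 1 without Gcn2+/+ Gars mutant replicate 1, Gcn2-/-, wild-type Gars replicate 3 or Gcn2-/- Gars mutant replicate 4, and rose to 6 without Gcn2+/+ Gars mutant replicate 3. With the Schwann score the motor neuron list had a median difference of 0.23 and an adjusted p of 0.0221 with an estimated correlation. All 3 Gcn2-/-, wild-type Gars libraries carry the earlier title numbers, against 2 of the 5 Gcn2-/- Gars mutants, so these numbers are not balanced in this difference. Among earlier libraries alone, the median Gars effect on motor neuron genes was -0.08 in Gcn2-/- mice. In Gcn2+/+ mice it was -0.37, with 1 wild-type library.

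**Figure D2:**
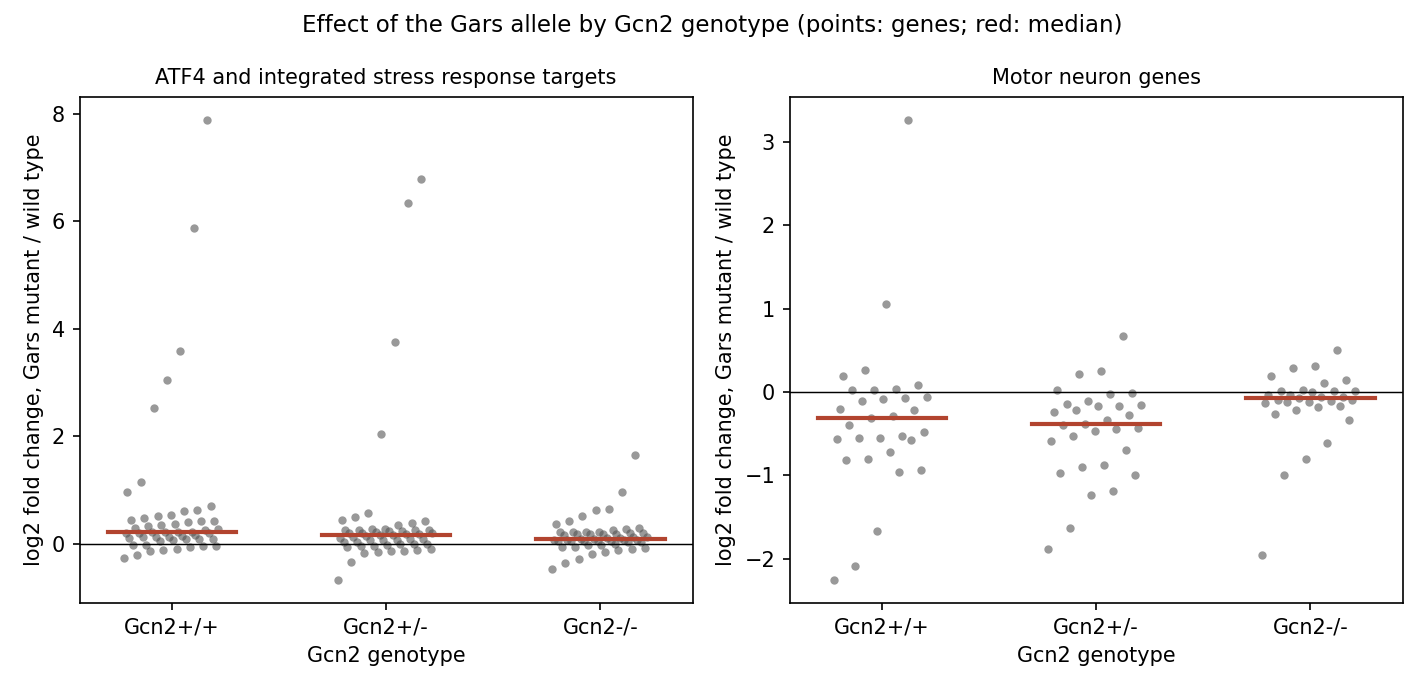
Log2 fold change between mutant and wild-type Gars of each gene of 2 lists, by Gcn2 genotype, with a red bar at the median. The median of the stress response targets was 0.22 in Gcn2+/+, 0.16 in Gcn2+/- and 0.10 in Gcn2-/- mice, and that of motor neuron genes -0.31, -0.38 and -0.07.

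With wild-type Gars, few genes were called for loss of Gcn2. With 3 against 4 animals, a low count does not show that little changed. Eif2ak4 fell by 1.21 on the log2 scale (SE 0.10, adjusted p = 7.32e-07), and 3 of the 5 called genes lay within 20 Mb of it on chromosome 2. The others there were Pla2g4e, a phospholipase gene, at -2.61 ± 0.22 and Ganc, an alpha-glucosidase gene, at -0.70 ± 0.11. Gfra4, also inside the window, was at 0.74 and not called (adjusted p = 0.265). Gm13328, on the same chromosome, fell and Gm15163 rose, both provisional genes named after their values were seen. Of the 51 stress response targets 0 were called, none over the list alone, with Trib3, a pseudokinase induced by ATF4, at -1.13 ± 0.43 and the arginine transporter gene Slc7a1 at -0.17 ± 0.08. Of 18 genes of eIF2 kinases, eIF2B and their regulators other than Eif2ak4, 0 were called, with Gcn1l1, the Gcn2 activator, at -0.07 ± 0.05.

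Microglia genes (20 tested, 19 below 0, median -0.33) and bone marrow and neutrophil genes (9 tested, all above 0, median 1.89) had 0 called members, none over the list alone, and an adjusted p of 0.955 each with an estimated correlation, with Tmem119 at -0.53 ± 0.24 and Ngp at 2.86 (adjusted p = 1). Removing Gcn2-/- replicate 1 gave 10 calls, removing Gcn2-/- replicate 3 gave 3, and removing wild-type replicate 4 gave 8. All 3 Gcn2-/-, wild-type Gars libraries carry the earlier title numbers, as does 1 of the 4 wild-type libraries, so that a difference between these sets of libraries and the loss of Gcn2 cannot be fully separated here.

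In Gars mutants, loss of Gcn2 lowered stress genes and raised motor neuron genes. Fgf21 had 452 counts over 4 mutants with Gcn2 and 1 count over 5 without, a ratio of 553 (95% interval 98.7 to 21877), and Adm2 was at least 45.6-fold lower, with 0 counts in Gcn2-/- mutants set at 3 counts over the group. Cdsn (-3.83 ± 0.35 on the log2 scale), Nupr1 (-2.22 ± 0.45) and, on chromosome 2, P2rx3 (-1.71 ± 0.19) fell. Nupr1 lost that call in 8 of 22 alternatives. Chodl rose by 1.47 ± 0.20, Slc10a4 by 0.99 ± 0.15 and Kcnj14 by 1.00 ± 0.12. Eif2ak4 itself was at -1.29 ± 0.08.

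Of the 51 stress response targets 8 fell and 0 rose (12 down and 1 up when adjusted over the list alone; median -0.15; adjusted p = 0.0278 with an estimated correlation), and of the 9 neuropathy stress genes 5 fell (8 over the list alone; median -1.82; adjusted p = 2.10e-04). Sesn2 (-0.45 ± 0.09) and B4galnt2 (-3.63 ± 0.56) were among those that fell. Of 31 motor neuron genes 8 rose and 0 fell (12 up and 3 down when adjusted over the list alone; median 0.22; adjusted p = 0.00495 with an estimated correlation), among them Nefh (0.50 ± 0.07), Chat (0.45 ± 0.07) and Prph (0.66 ± 0.11). Of 16 pan-neuronal genes 0 were called and 2 were up over the list alone (median 0.11, adjusted p = 0.273 with an estimated correlation), with Snap25 of the synaptic vesicle machinery, also on chromosome 2, at 0.31 ± 0.09. Sensory neuron genes had 2 of 11 down, P2rx3 and Avil (-2.80 ± 0.39), 2 also over the list alone, and an adjusted p of 0.294 with an estimated correlation. Further increases were those of Grin3b (0.71 ± 0.10), a subunit of NMDA receptors, Cd24a (0.74 ± 0.11), Layn (0.86 ± 0.14) and Popdc3 (0.89 ± 0.16). Further decreases were those of Stbd1 (-1.22 ± 0.21), Tead3 (-0.66 ± 0.15), Cyb5r1 (-0.41 ± 0.09) and Slc7a1 (-0.34 ± 0.07).

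Reactive astrocyte genes were lower in median (-0.68, 1 of 18 down, 8 over the list alone), the 1 called member being Cd44, a hyaluronan receptor gene on chromosome 2 (-0.78 ± 0.17). Schwann cell genes (-1.58, 0 of 19 called, 12 down over the list alone) and meningeal genes (-2.49, 0 of 22 called, 19 down over the list alone) lay lower too. Their adjusted p values were 0.238, 0.342 and 0.412 with an estimated correlation. In all 86 genes were called, 41 up and 45 down, 28 of them inside the window around Eif2ak4. With these 2 groups alone in the fit 21 were called, 4 up and 17 down, and with DESeq2 244. Without the genes of chromosome 2 there were 40, and with the Schwann score 33. In that last alternative the stress response list had an adjusted p of 0.0393 and the motor neuron list 0.00459 with an estimated correlation. Single libraries moved the count to 47 without Gcn2+/+ mutant replicate 4, and to 55 and 52 without Gcn2-/- mutant replicates 4 and 5.

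Averaged over both Gars genotypes, the calls of the Gcn2 knockout lay mostly on its own chromosome. Of 108 called genes, 61 up and 47 down, 88 lay on chromosome 2, between 20.2 and 164.9 Mb, and 51 of these within 20 Mb of Eif2ak4. Inside that window 15.6% of 327 tested genes were called, and outside it 0.333% of 16816 (Fisher's exact test, two-sided, odds ratio 55.1, p = 1.60e-59). Among the genes outside the window that rose were Ahcy (1.72 ± 0.29), which splits S-adenosylhomocysteine, Pcsk2os1 (1.17 ± 0.15), an RNA antisense to Pcsk2, Zhx3 (0.96 ± 0.17), Snhg17 (0.87 ± 0.15) and Dbndd2 (0.76 ± 0.14), all on chromosome 2. Inside the window Pla2g4e was at -2.70 ± 0.14, Ganc at -0.67 ± 0.07 and Gfra4, a receptor gene of the GDNF family, at 0.87 ± 0.10.

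Off that chromosome, Eif3j2, of chromosome 18 (-0.93 ± 0.13), Cd209c (-1.37 ± 0.26), Stbd1 (-0.74 ± 0.16) and Dlk2 (-0.71 ± 0.15) fell, while Cd24a rose by 0.40 ± 0.08. Eif3j2 shares a near-identical transcript with Eif3j1 of chromosome 2, so its own level is uncertain. Of the 51 stress response targets 4 fell, 11 when adjusted over the list alone, with an adjusted p of 0.0665 with an estimated correlation. They were Cdsn (-1.81 ± 0.27) and Slc7a1 (-0.26 ± 0.05), and, on chromosome 2, Trib3 (-1.48 ± 0.28) and the glutathione-degrading Chac1 (-0.45 ± 0.10). The averaged fall of Cdsn came from the Gars mutants, where it was at -3.83. Of the 9 neuropathy stress genes 2 fell, the same Trib3 and Chac1, 8 over the list alone (adjusted p = 0.00125 with an estimated correlation). Of 31 motor neuron genes 2 rose, 8 over the list alone, Nefh (0.23 ± 0.05) and, on chromosome 2, Mmp9 (0.34 ± 0.07), with an adjusted p of 0.0738 with an estimated correlation. Of 18 genes of eIF2 kinases and eIF2B 0 were called, with Eif2ak2 at -0.15 ± 0.10. The count was 68 and 69 without Gcn2-/-, wild-type Gars replicates 2 and 3, and 67 with the Schwann score.

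**Figure D3:**
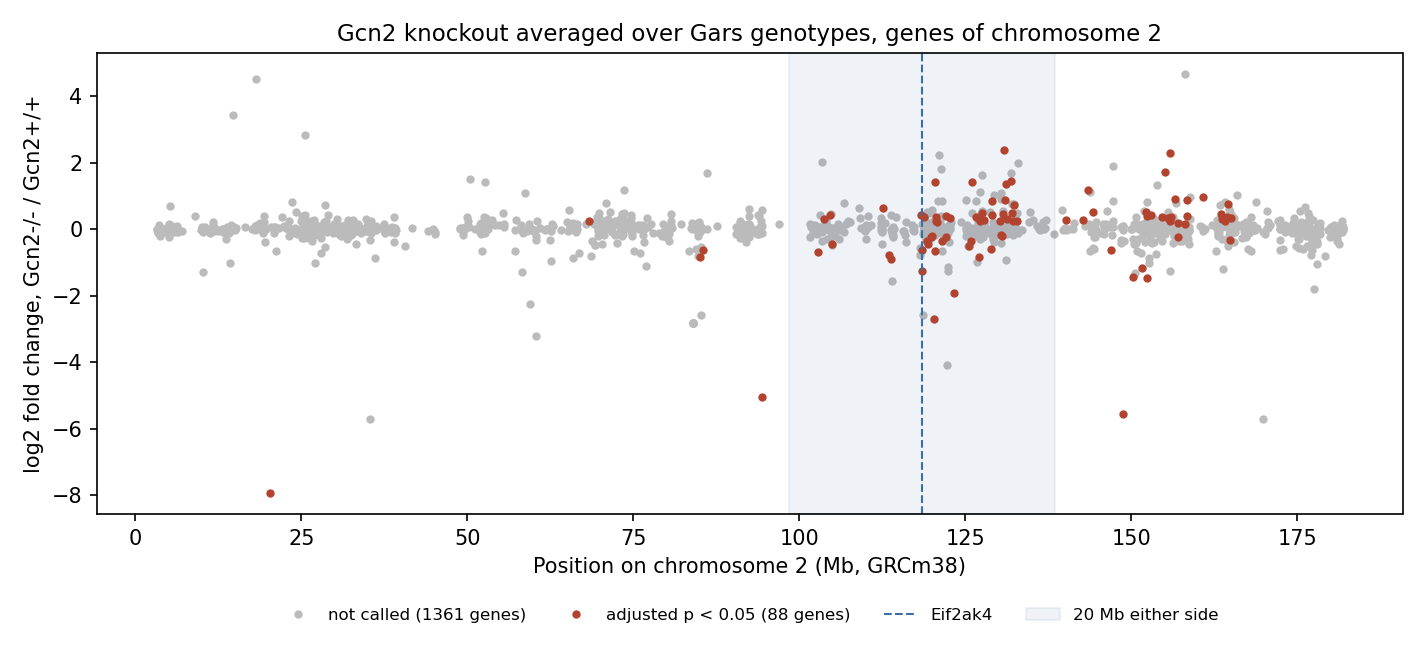
Log2 fold change of the Gcn2 knockout, averaged over the Gars genotypes, of each tested gene of chromosome 2 by its position in Mb on GRCm38; called genes are coloured, and the dashed line and band mark Eif2ak4 and 20 Mb to each side. The 88 called genes of this chromosome lie between 20.2 and 164.9 Mb.

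The double mutant was set against wild-type mice to show what remained of both alleles together. Calca (-2.29 ± 0.18 on the log2 scale, adjusted p = 1.20e-07), Calcb (adjusted p = 1.05e-04) and Uts2b (-1.19 ± 0.25) fell, while Fgf21 had 1 count in each group. Atf4 rose by 0.29 ± 0.06 (adjusted p = 0.0383), the 1 called member of the 51 stress response targets (1 up and 1 down when adjusted over the list alone; median 0.07; adjusted p = 0.927 with an estimated correlation). Trib3 was at -1.41 ± 0.36 and Sesn2 at 0.18 ± 0.08. Of the 9 neuropathy stress genes 0 were called and 1 was down when adjusted over the list alone, with Ddit3, the stress transcription factor CHOP, at 0.24 ± 0.12.

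Of 31 motor neuron genes 2 fell and 1 rose, Mmp9 of chromosome 2 (0.64 ± 0.10), and 6 fell and 1 rose when adjusted over the list alone, with a median of -0.15 and an adjusted p of 0.359 with an estimated correlation. Pappa, a protease that frees insulin-like growth factor (-0.66 ± 0.10), and the mitochondrial S-adenosylmethionine carrier gene Slc25a26 (-0.79 ± 0.16) fell, and Skor2 rose by 0.64 ± 0.14. Of 23 cholesterol biosynthesis genes 0 were called, none over the list alone, and 21 lay below 0 (median -0.19, adjusted p = 0.927 with an estimated correlation). In all 70 genes were called, 37 up and 33 down, and 24 without chromosome 2. With these 2 groups alone in the fit 27 were called, 8 up and 19 down, with the 4 listed genotypes 37, with the title number as a block 142 and with DESeq2 195. The count was 34 and 36 without wild-type replicates 2 and 3 and 43 without double mutant replicate 2.

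In Gcn2+/- mice, whose groups the design text does not list, mutant Gars also raised stress genes and lowered motor neuron genes. Fgf21 had 197 counts over 4 Gars mutants and 1 over 4 mice with wild-type Gars, a ratio of 172 (95% interval 30.5 to 6831), and Adm2 was at least 11.9-fold higher, against 0 counts set at 3 over the group. Cdsn rose by 2.05 ± 0.37 and P2rx3 by 1.19 ± 0.21. Calca (-1.88 ± 0.19), Prph (-0.97 ± 0.11), Calcb (-1.24 ± 0.16), Chodl (-1.19 ± 0.20) and Kcnj14 (-0.63 ± 0.12) fell. Eif2ak4 was at -0.46 to -0.51 against Gcn2+/+ mice, with adjusted p of 0.0952 and 0.113.

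Motor neuron genes fell in 10 of 31 cases and rose in 0, and 16 fell and 2 rose when adjusted over the list alone (median -0.38, adjusted p = 7.61e-04 with an estimated correlation), with Chat at -0.53 ± 0.07. Of the 51 stress response targets 3 rose, 13 over the list alone (median 0.16; adjusted p = 8.73e-07 by camera and 0.166 with an estimated correlation), and of the 9 neuropathy stress genes 2 rose, 6 over the list alone (median 0.45, adjusted p = 0.0133 with an estimated correlation). Gdf15, a stress hormone, had 25 counts against 1, a ratio of 21.8 (3.57 to 897), with an adjusted p of 0.189. Of 23 tRNA synthetase and export genes 0 were called and 2 were up over the list alone (adjusted p = 0.561 with an estimated correlation), with Cars at 0.32 ± 0.07 (0.072). Papss2 (0.80 ± 0.16), of sulfate activation, and Mapk8 (0.37 ± 0.07), the JNK1 gene, rose, while Layn (-0.86 ± 0.15) and Susd2 (-0.66 ± 0.11) fell.

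The mean log2 CPM of Schwann cell genes was 4.10 and 4.57 in wild-type Gars replicates 1 and 3 and 2.92 in Gars mutant replicate 4. Schwann cell genes (median -1.22, 0 called, 8 down over the list alone), meningeal genes (-1.59, 0 called, none over the list alone) and mitochondrially encoded genes (0.28, 0 called, none over the list alone) had adjusted p of 0.928, 0.928 and 0.696 with an estimated correlation. Pmp2, of peripheral myelin, was at -5.09 ± 1.67 and Islr at -2.76 ± 1.07. In all 31 genes were called, 9 up and 22 down, and 17 with the Schwann score. With these 2 groups alone in the fit 5 were called, 1 up and 4 down, and with DESeq2 190. With the title number as a block 4 were called, 0 up and 4 down, so none of the genes that rose kept its call. The 2 groups share no title number, so that fit compares them only through the other groups. The count was 66 without Gars mutant replicate 1, 20 without mutant replicates 3 or 4, and 18 without wild-type Gars replicates 2 or 4.

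The Gars effect in Gcn2+/- mice was compared with that in Gcn2+/+ mice by the same kind of difference. Genes of peripheral nerve and meninges differed most by fold among the lists. Of 19 Schwann cell genes 11 were down, 14 over the list alone (median -3.03), among them the peripheral myelin genes Prx (-11.19 ± 2.59) and Cldn19 (-10.15 ± 2.36). Of 22 meningeal genes 5 were down, 20 over the list alone (median -4.04), such as the small proteoglycan gene Ogn (-8.39 ± 2.01). Both had an adjusted p of 0.955 with an estimated correlation. Of the 13 mitochondrially encoded genes 1 was up, mt-Atp8 (4.10 ± 0.90), 10 over the list alone (median 0.54, adjusted p = 0.955 with an estimated correlation). The genes of smallest p were Fgf9 (0.56 ± 0.08, adjusted p = 0.018), a growth factor gene, the kinase gene Ttbk2 (0.51 ± 0.08), Pcsk1n (-1.18 ± 0.20), the pseudogene Gm13835 (3.62 ± 0.63) and the RNA-binding protein gene Tia1 (0.73 ± 0.13), the last 4 at 0.0399.

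Of 51 stress response targets 1 was down, Nupr1 (-2.41 ± 0.65, adjusted p = 0.047), 5 over the list alone (median -0.09, adjusted p = 0.955 with an estimated correlation), and of the 9 neuropathy stress genes 0, 1 over the list alone (median -0.17, adjusted p = 0.955). Among the 31 motor neuron genes 2 were up and 2 down, 4 and 2 over the list alone (median -0.03, adjusted p = 0.955), with the choline transporter gene Slc5a7 at 0.70 ± 0.18 and Sncg at -0.53 ± 0.13. In all 644 genes were called, 427 up and 217 down. The count was 3 with voom, 10 without a filter on low genes, and 0 with a Schwann gene score as a covariate, with the title number as a block or with the other groups left out of the fit. It was 1784 without wild-type replicate 1, 1596 without Gcn2+/- Gars mutant replicate 1, 307 without Gcn2+/+ Gars mutant replicate 1, and 358 and 77 without Gcn2+/-, wild-type Gars replicates 2 and 4. It was 0 without wild-type replicate 4, Gcn2+/+ Gars mutant replicate 2 or Gcn2+/- Gars mutant replicates 2 or 3, 1 without wild-type replicate 2, Gcn2+/+ Gars mutant replicate 3 or Gcn2+/- Gars mutant replicate 4, 2 without wild-type replicate 3 or Gcn2+/+ Gars mutant replicate 4, and 3 without Gcn2+/-, wild-type Gars replicate 3.

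No gene was called for the loss of 1 copy of Gcn2 with either Gars genotype. Eif2ak4 itself was missed, at -0.46 with wild-type Gars (adjusted p = 0.0952) and -0.51 with mutant Gars (0.113). With wild-type Gars its libraries ran from 21.5 to 23.6 CPM in Gcn2+/- and from 28.9 to 34.4 in Gcn2+/+ mice. A count of 0 therefore does not show that nothing changed. With wild-type Gars 0 genes were called by edgeR, with 3001 at an unadjusted p below 0.05, 457 called by DESeq2 and 0 by voom. The 19 Schwann cell genes (median 1.38, 0 called, 13 up over the list alone) and 22 meningeal genes (2.03, 0 called, 11 up) lay higher, both with an adjusted p of 0.989 with an estimated correlation. None of the 51 stress response targets was called, none over the list alone (median 0.03), and Atf4 was at 0.22 ± 0.06 (adjusted p = 0.138). Without wild-type replicate 1 the count was 664, and without Gcn2+/- replicate 3 it was 1.

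With mutant Gars 0 genes were called by edgeR, with 1900 at an unadjusted p below 0.05, 16 called by DESeq2 and 1 by voom. The 9 neuropathy stress genes all lay below 0 (0 called, none over the list alone, median -0.51, adjusted p = 9.32e-06 by camera and 0.17 with an estimated correlation), with Fgf21 at -0.85 ± 0.36, Sesn2 at -0.25 ± 0.09 and Adm2 at -1.06 ± 0.45. The 51 stress response targets had 1 up and 1 down over the list alone (median -0.06, adjusted p = 0.631 with an estimated correlation), with Cdsn at -1.36 ± 0.32. Of 31 motor neuron genes 0 were called and 2 were up over the list alone, with Nefl at 0.26 ± 0.07 and Chodl at 0.72 ± 0.20. The 18 reactive astrocyte genes had a median of -0.51 (0 called, none over the list alone, adjusted p = 0.631 with an estimated correlation), with Lcn2 at -1.20 ± 0.38. Without Gars mutant, Gcn2+/+ replicate 1 the count was 1.

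Averaged over the 3 Gcn2 genotypes, mutant Gars called 78 genes, 27 up and 51 down. Calca (-2.03 ± 0.11, adjusted p = 3.66e-10), Calcb (-1.30 ± 0.09), Chodl (-1.20 ± 0.12), Uts2b (-1.15 ± 0.16), Vipr2 (-0.77 ± 0.12), a receptor of VIP, Ahnak2 (-0.73 ± 0.08), Pappa (-0.67 ± 0.06) and Prph (-0.59 ± 0.06) fell. Of 31 motor neuron genes 14 fell and 0 rose, 18 and 2 over the list alone (median -0.26, adjusted p = 2.93e-05 with an estimated correlation). Atf4 rose by 0.30 ± 0.04, Cdsn by 1.73 ± 0.22, Sesn2 by 0.34 ± 0.05, the neutral amino acid transporter gene Slc1a4 by 0.21 ± 0.04 and Pycr1 by 0.73 ± 0.14, and 8 of the 51 stress response targets rose, 18 over the list alone (median 0.16, adjusted p = 0.00102 with an estimated correlation). Of the 9 neuropathy stress genes 4 rose, 7 over the list alone (adjusted p = 1.30e-04), among them Chac1 (0.41 ± 0.08). Cdsn was at -0.46 in Gcn2-/- mice, so its averaged rise came from the other Gcn2 genotypes.

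Of 23 tRNA synthetase and export genes 4 rose, 6 over the list alone, namely Cars (0.28 ± 0.04), Mars (0.22 ± 0.03), Wars (0.15 ± 0.03) and Iars (0.17 ± 0.03), with an adjusted p of 0.121 with an estimated correlation. Stbd1 (1.13 ± 0.14), P2rx3 (1.07 ± 0.12), Gnb1l (0.61 ± 0.11) and Hrk (0.31 ± 0.07), a cell death gene, rose as well. Of 18 endothelial genes 0 were called and 3 were down over the list alone (median -0.07, adjusted p = 0.747 with an estimated correlation), with the tight junction gene Cldn5 at -0.29 ± 0.08. Inside the window around Gars 0 of 222 tested genes were called, against 77 of 16921 outside. Leaving out single libraries gave 57 to 91 calls.

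Libraries also differed by the number in their titles. The first principal component set the 12 libraries of the later numbers, with scores of -39.6 to -16.5, apart from the 12 of the earlier ones, with scores of 9.1 to 41.0. Within the later set the stress response targets had a median log2 difference between mutant and wild-type Gars of 0.34 with intact Gcn2, and in the earlier set, with 1 wild-type library, 0.13. Motor neuron genes had -0.30 and -0.37. The 2 Gars mutants of that later set had Schwann gene means of 4.13 and 4.84, against 1.31 to 1.38 in its wild-type libraries. Title number and nerve root tissue are therefore not separate in these values. In Gcn2+/- mice the values were 0.20 and 0.14 for the stress response targets and -0.33 in both sets for motor neuron genes. In Gcn2-/- mice only the earlier set held both Gars genotypes, with 0.15 and -0.08.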

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

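The tests of the Gcn2 knockout calls and of the title numbers, and the alternatives with a Schwann gene score, without chromosome 2 or with title numbers in 2 sets, were chosen after the results were seen, and the tests of nerve root tissue and depth and the regroupings of libraries before.

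Single libraries stood apart from the rest of their group in 19 of 150 groups of values tested. The rule flags about 1 in 20 groups of independent, normally distributed values. Many of these values share genes or tissue, and Fgf21 was flagged for 1 count against 0. The 19 can therefore not be weighed against that share. The group of 3 animals was not tested. Schwann cell content was a measure with libraries set apart. The mean log2 CPM of Schwann cell genes was 1.95 in Gcn2-/- Gars mutant replicate 5 and 2.92 in Gcn2+/- Gars mutant replicate 4. In Gcn2+/+ Gars mutant replicate 4, mitochondrially encoded genes averaged 11.4, pericyte genes 4 and pan-neuronal genes 8.46. In Gcn2+/-, wild-type Gars replicate 3, reactive astrocyte genes averaged 4.61 and activated microglia genes 4.71. In wild-type replicate 3, reactive astrocyte genes averaged 3.03 and genes of the unfolded protein response 6.31. The stress response targets averaged 4.46 in Gcn2+/+ Gars mutant replicate 1.

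Among single genes, Gars was at 134 CPM in wild-type replicate 1, Atf4 at 111 in Gcn2+/- Gars mutant replicate 1, Chodl at 20.5 in Gcn2-/- Gars mutant replicate 2, Calca at 17 in Gcn2+/-, wild-type Gars replicate 2 and Calcb at 4.56 in replicate 1 of that group. Fgf21 stood apart through 1 count in each of wild-type replicate 3 (0.0377 CPM), Gcn2-/- Gars mutant replicate 1 (0.031) and Gcn2+/-, wild-type Gars replicate 4 (0.0509). The total of 32.4 M counts in Gcn2-/- Gars mutant replicate 1 was apart from its group too.

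The Gars effect differed between Gcn2-/- and Gcn2+/+ mice by a test of the difference itself for 2 genes, Cdsn (-4.04) and Kcnj14 (1.19), and, with an estimated correlation, for the lists of neuropathy stress genes (median -0.70) and motor neuron genes (median 0.29). Of 60 splits of these libraries 4 gave as many calls, the highest of the others 28, so chance is not excluded for the number of calls. Between Gcn2+/- and Gcn2+/+ mice the effect differed for 644 genes, led by Fgf9 (0.56), Ttbk2 (0.51), Pcsk1n (-1.18), Gm13835 (3.62) and Tia1 (0.73). Only the real split of 60 gave as many, against 94 at most in the others. Those splits shuffled the Gars labels inside each Gcn2 genotype, which removes the whole Gars effect and not only its difference. They therefore do not show whether chance is excluded for that count. The Schwann gene score contrast was -3.14 in the real split and -0.6 in the split with 94 calls. The splits also leave the title number out of account. With that number as a block 0 genes were called, with Fgf9 at 0.57 (adjusted p = 0.382) and Tia1 at 0.78 (0.413). That fit also takes out Gcn2+/-, wild-type Gars replicate 3 and Gcn2+/- Gars mutant replicate 4, each the only library of its title number. Leaving out either one alone gave 3 and 1 calls. The 0 therefore cannot be put down to the title number, whose part in the count stays open.

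Those 644 calls were weighed against nerve root tissue and depth. With every library thinned to 19.7 M counts, 571 genes were called, which argues against depth as the cause. Nerve root tissue predicts the direction of each gene from its slope on the Schwann gene score inside groups, and 64% of the called genes went that way against 51.2% of other genes, with a score contrast of -3.14. That share lies between the bounds set for either answer, and the score is unevenly spread over the groups, so it stays open. With the score in the fit 0 genes were called, while the called genes' median absolute log2 difference went from 0.56 (median SE 0.14) to 0.51 (0.17) and 622 kept their direction, so the calls ended with a modest loss of size and a wider error. A biological effect of 1 Gcn2 copy stays open and untested here.

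The calls of the Gcn2 knockout averaged over Gars genotypes lay along chromosome 2. Of 1122 tested genes of that chromosome outside the window 37 were called, against 19 of 15694 on other chromosomes (odds ratio 28.1, Fisher's exact test, p = 2.22e-30), which is consistent with donor-strain sequence along the chromosome. Off it, 7 of 19 called genes (36.8%) matched a transcript of chromosome 2 between 80 and 170 Mb at 90% identity over 200 bases, against 1.9% of other genes (odds ratio 30.1, Fisher's exact test, p = 4.03e-08), so shared reads are a candidate explanation for them. Of the 7 best matches 2 lay outside the window around Eif2ak4, at 155.2 and 167.1 Mb. Among the matched genes Eif3j1 (0.40), Pcna (0.72) and Spg11 (-0.24) were called. Itch (0.01), Gm11472 (-0.08) and Nop56 (0.09), which matched Gm9432 and Gm27219, were not. Loss of the stress response has support in 2 further genes, Cdsn and Slc7a1 (odds ratio 39.9, Fisher's exact test, p = 0.00152). Cdsn fell with loss of Gcn2 in Gars mutants (-3.83) but not with wild-type Gars. There it had 0.192 to 0.267 CPM with Gcn2 and 0.249 to 0.336 without. Slc7a1 was at -0.17 with wild-type and -0.34 with mutant Gars. These explanations cover different genes and do not exclude each other.

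Libraries of earlier and later title numbers differed in 584 genes. Of those with a position, 66.3% lay within 1 Mb of another, against 52.3% in random sets and at most 60.1% in 1000 of them, a ratio of 1.27. Pseudogenes made up 11.5% of them against 3.44% of tested genes. Strain background and a change of library kit or reagents cannot be told apart here, because the ratio lies between what each needs and neighbouring genes also share base composition. The labels tie neither to single libraries, and no biological explanation was tested.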

How the results depend on the processing

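The alternatives with title numbers in 2 sets, with a Schwann gene score and without chromosome 2 were chosen after seeing the data, and the others before. No paired analysis was possible by replicate number, because these follow the order of the labels and pair no libraries. Title numbers, which some libraries of different groups share, were fitted as a block. The alternative with the 4 listed genotypes gives no value for comparisons with Gcn2+/- mice. The cause of the changes below was not tested, except where fewer genes or libraries were used.

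Counts of called genes moved by more than 1.5 times as follows. For the Gars effect with intact Gcn2, 110 became 201 without the sex term, 57 with the 4 listed genotypes, 11 with its own groups alone, 663 with DESeq2, 72 without a filter and 39 with the Schwann score. In Gcn2-/- mice, the Gars effect's 2 became 32 with DESeq2 and 1 with the 4 genotypes, its own groups, the title block, a surrogate variable or title numbers in 2 sets. For the difference between these, 2 became 8 without the sex term, 35 with DESeq2, 7 with voom, 0 with the title block and 1 with a mean CPM of at least 1, title numbers in 2 sets or the Schwann score.

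For the Gcn2 knockout with wild-type Gars, 5 became 12 with its own groups, 37 with DESeq2, 8 with the title block, 2 without the windows and 1 without chromosome 2. In Gars mutants 86 became 21 with its own groups, 244 with DESeq2, 33 with the Schwann score and 40 without chromosome 2. For the double mutant 70 became 37 with the 4 genotypes, 27 with its own groups, 195 with DESeq2, 142 with the title block and 24 without chromosome 2. For the knockout average 108 became 203 with DESeq2, 67 with the Schwann score, 57 without the windows and 20 without chromosome 2.

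In Gcn2+/- mice, the Gars effect's 31 became 5 with its own groups, 190 with DESeq2, 4 with the title block and 17 with the Schwann score. Its difference from Gcn2+/+ mice, 644, became 1713 with DESeq2, 3 with voom, 10 without a filter and 0 with its own groups, the title block or the Schwann score. For 1 lost Gcn2 copy, 0 became 457 with DESeq2 and 3 with the title block with wild-type Gars, and 16 with DESeq2, 1 with voom and 2 with its own groups or the title block with mutant Gars. The Gars average, 78, became 200 with DESeq2. Of the list tests 118 passed with the preset correlation, 14 with an estimated one, 21 with fry in 1 direction and 58 with fry in either.

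Leaving out 1 library gave 47 to 600 calls for the Gars effect with intact Gcn2, 1 to 2 in Gcn2-/- and 18 to 66 in Gcn2+/- mice, and 57 to 91 for its average. It gave 0 to 6 and 0 to 1784 for the differences from Gcn2+/+ mice with 0 and 1 copies. It gave 3 to 10 and 47 to 85 for the knockout with wild-type and mutant Gars, 68 to 117 for its average, 34 to 102 for the double mutant, and 0 to 664 and 0 to 1 for 1 lost copy with wild-type and mutant Gars.

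Of 192 called values of named genes, 188 stayed called without the sex term, 160 with voom and 106 with the title block, and of 191, 92 with their own groups alone. With the Schwann score 57 lost their call and 6 more changed sign in the difference between Gcn2+/- and Gcn2+/+ mice and were not called, namely Aldh1a2 (0.40), Cldn19 (0.11), Egr2 (0.87), Slc13a4 (0.14), Ogn (0.74) and Dcn (0.39). Depth limits Fgf21, Adm2 and Gdf15, whose lower groups hold 0 or 1 counts.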

Other observations

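The regroupings of libraries were chosen before the results were seen.

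Other splits of the same libraries were refitted. For the Gars effect with intact Gcn2 the real split, with 110 calls, was 1 of 35 with as many, the highest other giving 3. For the Gcn2 knockout in Gars mutants (86 calls), the double mutant (70) and the knockout average (108) it was 1 of 60, with 9, 10 and 3 in the highest others. For the Gars effect in Gcn2+/- mice (31) it was 1 of 35, with 2. With 35 splits no share below 1 of 35 is possible. Each count exceeded those of all other splits fitted, which makes chance an unlikely source in such splits. They leave the title number and nerve root tissue out of account. The Schwann gene score contrast was 1.87 for the Gars effect with intact Gcn2, against 0.13 in the highest other split. It was -1.77 against 1.29 for the knockout in Gars mutants and -1.27 against -0.15 in Gcn2+/- mice. For the double mutant and the knockout average it was 0.1 against -0.2 and -0.87 against -0.86. With the score in the fit the counts were 39, 33, 17, 86 and 67 in that order, so a part of such tissue stays open. With the title number as a block the count in Gcn2+/- mice was 4. Fold changes moved less over all alternatives, that block included. P2rx3 lay at 1.01 to 1.35, Cdsn at 1.87 to 2.30, Chodl at -1.39 to -0.96 and Kcnj14 at -0.75 to -0.54. These groups share no title number, so a part of that number in the count stays open. For the Gars effect in Gcn2-/- mice 2 of 56 splits, the real one included, gave at least 2 calls. That share lay below the bound set beforehand, but the other split gave 31, so chance is not excluded for a count of 2. The highest, with 31, set the 3 libraries of title number 24906 against the other 5, so it follows the title number, and with that number as a block 1 gene was called.

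For the Gars average, 78 calls, 2 of 60 splits gave as many, a share below the bound set beforehand. Chance is still not excluded for the count, because the other split gave 755 calls and points to a structure of the samples. It set 9 libraries of earlier and 4 of later title numbers against the rest, where the real split has 6 and 7, so it follows the title number in part. Its contrast in the Schwann gene score was -0.95, against 0.23 in the real split. With the title number as a block the real split gave 78 calls. For the Gcn2 knockout with wild-type Gars, 5 calls, 3 of 35 splits gave as many, the highest other 6, so chance is not excluded. That split set the 3 females against the 4 males. With 1 Gcn2 copy lost, 0 genes were called by edgeR with wild-type Gars (3001 at an unadjusted p below 0.05, 457 by DESeq2, 0 by voom) and with mutant Gars (1900, 16 and 1). With 0 calls all 35 splits of each give as many by construction (the highest other 1), so they say nothing about chance.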
